A study of Caenorhabditis elegans with 3 samples.

How the data were processed

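RNA of young adult Caenorhabditis elegans was compared on 2-colour DNA microarrays. Each of 3 arrays carried cDNA of a transgenic strain that expressed a fusion of the protein kinase D homologue DKF-2 with GFP from the dkf-2 promoter in a wild-type background, labelled with Cy5, and cDNA of the wild-type strain N2, labelled with Cy3. Per the labels' protocols, worms were grown at 20 °C on E. coli OP50 and collected as young adults at 20 h past the L4 stage, RNA was extracted with Trizol and an RNeasy column, and 20 µg of total RNA was reverse transcribed with Cy3- or Cy5-tagged dUTP. Per the labels, the 3 arrays were 3 independent biological replicates, and both strains of a replicate were grown and harvested in parallel. The dyes were swapped on 0 arrays.

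The authors deposited 1 log2 ratio per probe and array, printed to 5 decimals. The scanner, the background correction and the normalization are not given in the sources used here. The table held 22370 probes, of which 6 had no value on any array, and 22364 had a value on all 3. The array medians were 0.20, 0.21 and 0.12 for replicates 1, 2 and 3, so the deposited ratios were not centred on 0. The direction of the ratio is not stated in the table. It is taken here as transgenic over wild type, which is likely because the sample descriptions set the transgene against the wild type and the transgenic strain is channel 1.

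The log base was read from the values. Many probes of an array shared a value to all 5 decimals with more other probes than the local density of values allows (Poisson p under 0.01). These shared values made up 36.8%, 35.5% and 30.6% of the probes on the 3 arrays, as ratios of low whole-number intensities would. Spots with the same product of both intensities receive the same intensity-dependent correction, so their log2 ratios differ by the log2 of a squared ratio of whole numbers. Differences between shared values fell on such squares 1.83, 1.96 and 1.76 times as often as chance on the 3 arrays, against 0.90 to 1.09 times for the natural logarithm and 1.04 to 1.15 times for log10. The factor of 2 from the square is not a factor on the ratios themselves: values at 2 times the log2 ratio would meet the fourth powers (0.77, 0.62 and 0.92 times chance here, against 1.95 in a simulation of that scale) or, with a constant correction, the squares (20.9 times in a simulation). A simulation of log2 ratios with an intensity-dependent correction gave 1.46 times for the squares and 0.97 for the fourth powers. A shared value was taken as a mark of a dim spot. The table holds no intensities, so signal over background is unknown, and the number of arrays limits the precision. In simulated whole-number intensities without an intensity-dependent correction, probes marked in this way had a median intensity of 36.6 counts against 581 for the rest. The intensity of marked probes under such a correction was not examined.

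Probes were named through the platform annotation given with the series, whose Entrez numbers were looked up in a RefSeq gene table of assembly WBcel235. Of the 22370 probes, 8757 had 1 gene symbol, 0 had several and 13613 had none. For 8724 of the named probes the Entrez number was found in the RefSeq table, and 0 symbols differed. Probes of the same named gene were averaged (467 genes had several probes, and 4 of these had probes called in opposite directions), which left 8187 named genes and 13607 unnamed probes. The probe of dkf-2 and those of its relatives and of the p38 pathway are unnamed here and were not analysed by name. Probe sequences were not used here, so cross-hybridisation within gene families was not assessed.

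Each array is a ratio within a replicate, so the test was an intercept-only model against 0 over the 3 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 21794 genes and unnamed probes and a threshold of 0.05. The prior SD was 0.396 with 2.69 prior degrees of freedom. Genes at least 2-fold away from equality on every array were counted without a model. Gene lists were compared with all other named genes by limma's camera with a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives, the latter also on arrays centred on the median of the named genes, chosen after seeing the data. With an estimated correlation camera rests on the few residual degrees of freedom of 3 arrays, so small p-values are hard to reach there. Of 40 lists fixed before the data were examined, 4 had 5 or more measured genes and were tested, 10 had 1 to 4 and 26 had none, since most genes with long-established names are unnamed here. Families of 10 or more genes with the same name stem were tested in the same way (17 families); a search over families of 4 or more (56 families) was chosen after seeing the data.

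The named genes were chosen by a rule fixed before the data were examined: the 15 largest rises and the 15 largest falls among named genes past the threshold with the same sign on every array, and for each fixed list the 4 largest called members or, if none was called, the 2 with the smallest p. Family members named beyond this rule were chosen after their values were seen. The alternatives were other normalizations between arrays, each probe on its own, a robust variance prior, array weights, other thresholds and each replicate left out. Alternatives chosen after seeing the data left out genes with a shared value on any array, centred arrays within classes of shared values, or removed the trend with gene length (the gene's span in the RefSeq table).

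The fit was tested on simulated ratios of 21794 genes with the spread seen between these arrays. Of 200 genes changed by 1 on the log2 scale, 61.0% were recovered; the share was 71.5% at 1.5, 86.5% at 2 and 94.0% at 3. Of the simulated calls, 3.13% to 3.58% fell on unchanged genes. These figures assume that 9000 other genes changed as well. They also assume that unchanged genes carry no offset of an array, no lean of dim spots and no dye effect. The deposited ratios were not centred and lay higher in genes with shared values. The simulated share therefore does not give the share of false calls among the calls made here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.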

Results

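Transcript levels were compared between young adult worms carrying a DKF-2-GFP transgene and wild-type N2 worms grown beside them. DKF-2 is a protein kinase D homologue, a class of kinases that act downstream of diacylglycerol and protein kinase C. The comparison asks which transcripts differ between worms with the added DKF-2-GFP and wild-type worms. Whether DKF-2 was elevated could not be read from the probes named here. There was 1 group of 3 biological replicates, with 1 array of 22364 measured probes for each. Positive log2 ratios mean higher in the transgenic strain, a direction that is likely from the sample descriptions and was not stated with the values. The transgene's own gene could have served as a check of the direction, but its probe is unnamed here and was not analysed.

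Among named genes that passed the test, the largest rises in the transgenic worms were found mostly in genes known by sequence name. The 13607 unnamed probes were not ranked. F11D11.3 was higher by 5.44 ± 0.32 on the log2 scale (SD, n = 3), 43.3-fold, and C07G1.7 by 5.15 ± 0.17, 35.5-fold. ZK177.9 was higher by 4.31 ± 0.72. These 3 genes had limma adjusted p-values of 0.0198, and none had a shared value, the mark of a dim spot used here. The other 12 of the 15 largest rises had a shared value on at least 2 arrays. Among these, W03C9.1 was at 4.52 ± 1.04, nduf-11, named as a subunit of respiratory complex I, at 3.96 ± 0.93, and F55G11.10 at 3.87 ± 0.14, while M04D8.5 at 4.40 ± 2.60 ranged from 1.58 to 6.70 between replicates and no longer passed once arrays were centred within classes of shared values (adjusted p = 0.0628), a setting chosen after seeing the data. B0207.6, K03H6.5, Y116A8B.1, C27A7.3, W05B10.4, F42A9.3, K05C4.7 and C32H11.7 had means between 3.87 and 4.13. The sizes and ranks of these 12 genes are poorly determined: 2 probes of a gene correlated with r = 0.02 over 136 genes with a probe that had a shared value on all 3 arrays.

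Among named genes that passed the test the largest falls were smaller, and none of the 15 genes had a shared value. Y106G6D.2 fell by 2.63 on the log2 scale with an SD of 1.29 (n = 3), gtnt-27 was at -2.61 ± 0.60 and F20G4.2 at -2.57 ± 0.66. The genes lrpr-1, picd-1 and gtap-1 followed at -2.43 ± 0.41, -2.40 ± 0.72 and -2.40 ± 0.50. ZK484.3 at -2.38 ± 0.17 and T16H12.3 at -2.37 ± 0.28 had small spreads between replicates. F02E9.3, T10E9.2, F10E9.4, C04E12.4, Y49E10.21, ZK632.11 and gldi-11 fell to means between -2.25 and -2.18. The adjusted p-values of these 15 falls lay between 0.0198 and 0.0334. The gene cip-2A, without a shared value, had a lower mean of -3.06 ± 2.14 but did not pass (adjusted p = 0.0588); in the refit on genes without a shared value, chosen after seeing the data, it passed (adjusted p = 0.00917).

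**Figure D1:**
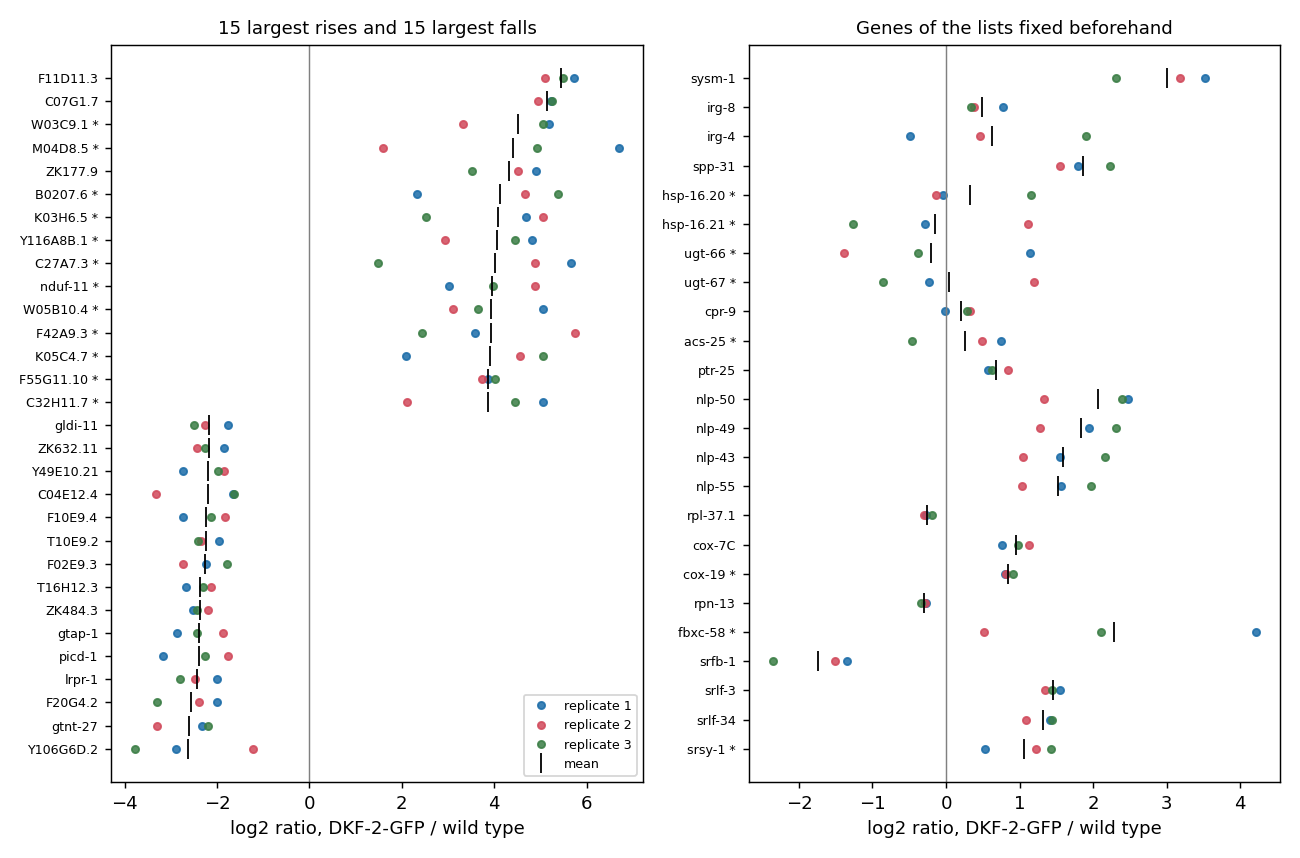
Log2 ratios (x axis) of each named gene (y axis) on the 3 arrays, as coloured points, with the mean as a black bar; an asterisk marks genes with a shared value on at least 1 array. F11D11.3, C07G1.7 and ZK177.9 lie above 3.5 on every array without a shared value, and the 15 falls lie below 0 on every array.

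Of the genes that respond to the p38 kinase PMK-1 in innate immunity, 5 could be measured by name, and 1 rose. This was sysm-1, a commonly used reporter of PMK-1 activity, at 3.00 ± 0.62 (n = 3, adjusted p = 0.0198), 7.99-fold higher. The other members did not pass the test: irg-4 was at 0.63 ± 1.21, irg-5 at -0.08 ± 0.27, C17H12.8 at -0.33 ± 0.12 and K08D8.5 at -0.82 ± 0.47. As a list the 5 genes did not stand apart from other named genes (camera adjusted p = 0.583). Their mean lay 0.19 above that of other genes, while their median of -0.08 lay below the others' median of 0.30, and camera's direction was down. Adjusted over the list alone, 1 gene was higher and 0 lower. By fry, which tests against 0 and not against other genes, the adjusted p was 0.0482, and 0.872 once each array was centred on the median of the named genes, a setting chosen after seeing the data that is used for fry below. Infection response genes fixed as a separate list had 3 measured members, irg-4, irg-5 and irg-8, and 0 passed the test (irg-8 at 0.49 ± 0.24, adjusted p = 0.129). The lowest limma adjusted p of irg-8 among the alternatives was 0.0493. Adjusted over the list alone, 0 passed. Of 2 saposin-like genes, whose family includes antimicrobial proteins, spp-31 rose by 1.86 ± 0.34 (adjusted p = 0.0202) and spp-24 was at -0.04 ± 0.19; adjusted over the list alone, 1 gene was higher.

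Of the 9 measured genes of the fixed neuropeptide list, 6 rose, 0 fell and 3 did not pass, and 9 of 9 had a positive mean. The largest rises that passed were nlp-50 at 2.07 ± 0.64, nlp-49 at 1.84 ± 0.52, nlp-43 at 1.59 ± 0.56 and nlp-55 at 1.52 ± 0.47 (n = 3 each). The gene nlp-45 had a higher mean of 2.28 ± 3.06 but did not pass (limma adjusted p = 0.206). It ranged from 0.34 to 5.80 and had a shared value on all 3 arrays. The list's mean lay 1.17 above that of other named genes (camera adjusted p = 0.00683). With the estimated correlation, 0.45, camera's adjusted p was 0.632. By fry the adjusted p was 0.0313, and 0.0542 after centring. The list's genes are short (median length 711 bp), and the shortest 428 named genes without a shared value had a median of 0.67; with the length trend removed, a setting chosen after seeing the data, the shift was 0.98 (camera adjusted p = 0.00590). Adjusted over the list alone, 8 genes were higher and 0 lower. All 24 measured genes of the nlp family, which include these 9, had a positive mean; 16 of them passed the test, among them nlp-80 at 1.81 ± 0.45, nlp-71 at 1.76 ± 0.36 and nlp-61 at 1.52 ± 0.22. The family's adjusted p was 6.26e-06 with camera, and 0.450 with the estimated correlation of 0.36.

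Among the other fixed lists, 7 genes of oxidative phosphorylation were measured, and 2 rose: cox-7C, a cytochrome c oxidase subunit, at 0.96 ± 0.19 and cox-19, named for an assembly factor of this enzyme, at 0.84 ± 0.05. The rest, with atp-1 at -0.67 ± 0.22 and cox-6C at 1.42 ± 0.91, did not pass. After centring of the arrays, cox-19 no longer passed (adjusted p = 0.0588). The list did not stand apart from other genes (camera adjusted p = 0.452), and adjusted over the list alone 4 genes were higher and 1 lower. By fry the adjusted p was 0.00358, and 0.00712 after centring. The list of chemoreceptor names held 31 genes, picked by the start of the name, so that it can hold genes of other kinds. Examples are srf-2 and srf-5, which are named for surface antigens. What the other names stand for was not checked here, those of the 2 genes that fell included. Of these 31 genes, 5 rose, among them srlf-3 at 1.45 ± 0.10, srlf-34 at 1.31 ± 0.20 and srsy-1 at 1.06 ± 0.47, and 2 fell, srfb-1 at -1.74 ± 0.54 and srrt-1 at -0.91 ± 0.29. After centring, srsy-1 no longer passed (adjusted p = 0.0710). The list as a whole did not stand apart from other genes (camera adjusted p = 0.452), and adjusted over the list alone 10 were higher and 3 lower. By fry the adjusted p was 0.00723, and 0.0412 after centring.

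For the remaining lists only 1 or 2 genes were measured by name, and 0 passed the test over all genes. The heat shock genes hsp-16.20 and hsp-16.21 were at 0.33 ± 0.72 and -0.14 ± 1.19, and the glucuronosyltransferases ugt-66 and ugt-67 at -0.21 ± 1.27 and 0.04 ± 1.05. The gut protease gene cpr-9 was at 0.20 ± 0.18, the acyl-CoA synthetase gene acs-25 at 0.25 ± 0.64 and the ribosomal protein gene rpl-37.1 at -0.26 ± 0.06. The proteasome subunit gene rpn-13 was at -0.30 ± 0.04, the F-box gene fbxc-58 at 2.28 ± 1.85 and the patched-related gene ptr-25 at 0.68 ± 0.14. Adjusted over the list alone, ptr-25 and fbxc-58, each the 1 measured gene of its list, passed. Among the alternatives, ptr-25 had a lowest limma adjusted p over all genes of 0.0127.

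Genes were also grouped by name stem. Of 17 families with 10 or more members, 7 stood apart from other named genes by camera with the preset correlation, 6 higher and 1 lower. With an estimated correlation 0 of the 17 passed (adjusted p = 0.450 for each of the 7). For clc the estimated correlation of -0.0035 lay below the preset 0.01, yet camera's unadjusted p rose from 0.000259 to 0.0589. For clc the lost call therefore does not show that correlation between genes made the shift. In the other families of the 7 the estimate lay above the preset, from 0.019 for nspg to 0.20 for nssp and 0.36 for nlp. There the lost calls may come from correlation, from the few degrees of freedom or from both. By fry 12 passed, and 0 after centring (lowest adjusted p 0.0563). Claudin-like genes (clc) were higher in 10 of 17 members and lower in 0, led by clc-32 at 3.86 ± 1.23, clc-11 at 3.80 ± 0.58, clc-19 at 2.15 ± 0.51 and clc-26 at 1.92 ± 0.02 (n = 3 each; family adjusted p = 0.000881). In the nspg family of nematode-specific peptides, 9 of 13 members rose, with nspg-8 at 2.16 ± 0.31 and nspg-12 at 1.80 ± 0.31 (adjusted p = 0.000637). The nssp family was the largest, with 31 of 55 members higher and 0 lower (adjusted p = 1.07e-06), led by nssp-87 at 2.40 ± 0.50. In the spig family 9 of 15 rose (adjusted p = 0.00869), and in the dbd family 3 of 13 (adjusted p = 0.0382). In dbd 10 of the 13 members had a shared value, and the call ended without replicate 3 (adjusted p = 0.0548), after centring within classes of shared values (0.109), without genes with a shared value (0.257, 3 members) and when adjusted over 56 families (0.0707). Carboxylesterases (cest) were lower in 10 of 31 members and higher in 0 (adjusted p = 0.000133), with cest-5.2 at -1.67 ± 0.55, cest-9.2 at -1.57 ± 0.42, cest-1.2 at -1.55 ± 0.24 and cest-2.1 at -1.22 ± 0.09. The pals genes, a family of the intracellular pathogen response, did not stand apart (24 members, 2 higher, 1 lower, adjusted p = 0.944).

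**Figure D2:**
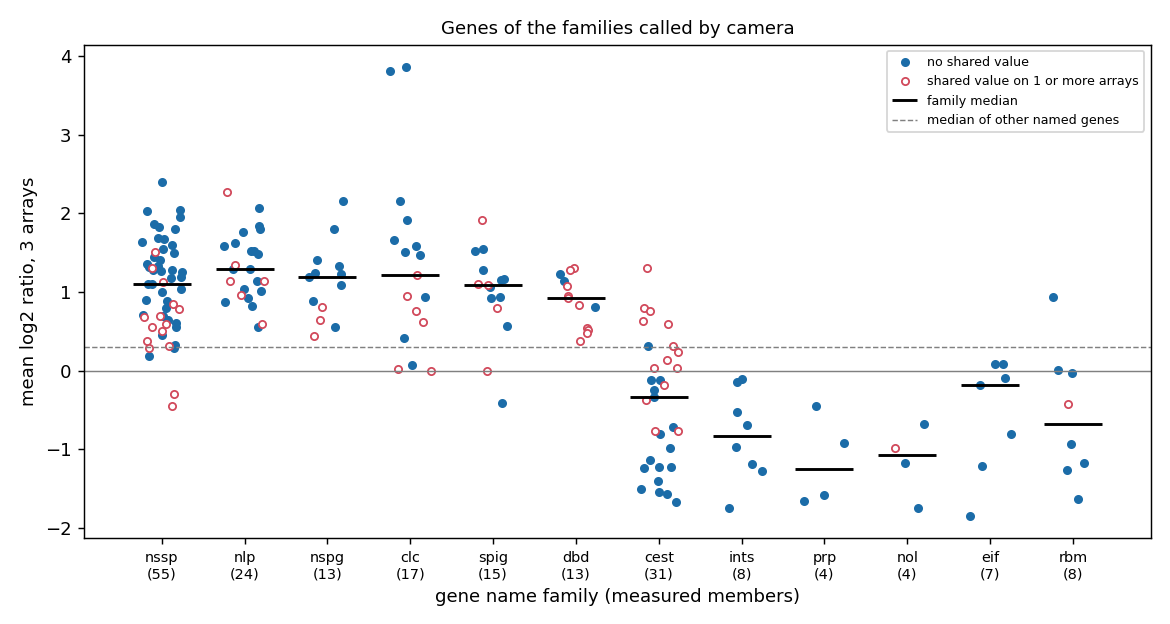
Mean log2 ratio over 3 arrays (y axis) of each gene in 12 families that passed camera's test, in the main search or in the search over smaller families (x axis, with the number of measured members); open points have a shared value on at least 1 array, black lines are family medians and the dashed line is the median of other named genes, 0.30. The 24 nlp genes all lie above 0, and the 8 ints and 4 prp genes all lie below 0.

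Over the whole array, 5007 of 21794 genes and unnamed probes passed the test (22.97%), 3045 higher and 1962 lower, so that 60.8% of the calls were higher; with the ratio turned the other way, 39.2% would be. Of the named genes, 1359 were higher and 603 lower. After each array was centred on its median, 1920 were higher and 2756 lower, or 41.1% higher, so the balance of rises and falls was not settled by these values; centring lowered every ratio of an array by its median over genes, 0.20, 0.22 or 0.12. With any 1 replicate left out, 0 genes passed limma's adjusted threshold, against 6739 to 7178 at an unadjusted p under 0.05. At least 2-fold differences on every array were found for 1277 genes in the higher and 787 in the lower direction, against a mean of 27.3 genes when the sign of 1 array was flipped. Across genes, which are not independent replicates, the arrays correlated with r of 0.55, 0.57 and 0.59, and 62.4% of the genes had the same sign on all 3 arrays, where chance gives 25%.

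The balance of calls differed with shared values, because lower calls were rarer among genes that had them. The 11925 genes with no shared value had a median log2 ratio of -0.03, and 1734 were higher and 1851 lower. The 4991 genes with a shared value on all 3 arrays had a median of 0.54, and 810 were higher and 7 lower. The median SD between arrays was 0.29 in the former and 0.57 in the latter. Where a gene had 2 probes, their mean ratios correlated with r = 0.73 over 127 genes without a shared value, and with r = 0.02 over 136 genes with a probe that had a shared value on all 3 arrays. Refitted on genes without a shared value, 6215 passed the test, 3005 higher and 3210 lower, and these included all 3585 calls that such genes had in the fit over all genes. Of the named genes in this refit, 1342 were higher and 1008 lower.

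**Figure D3:**
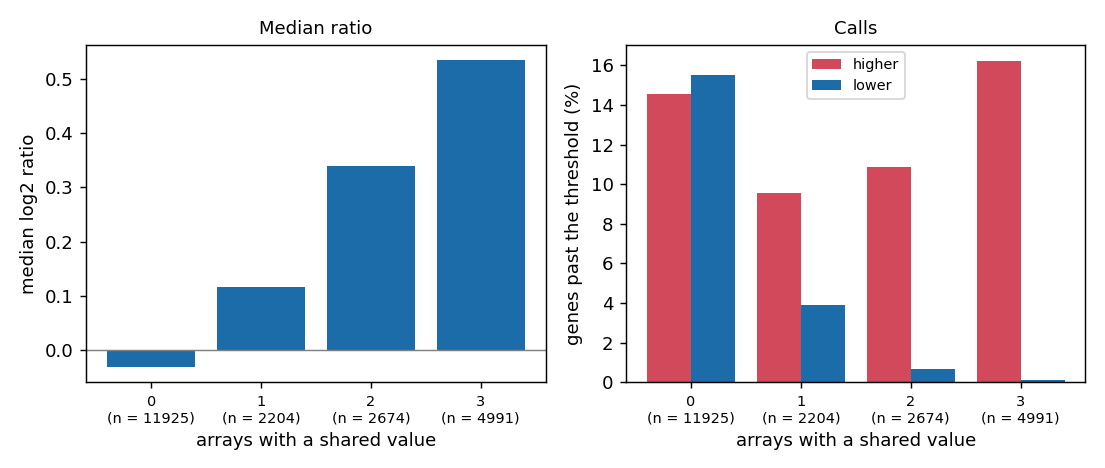
Median log2 ratio of genes (left, bars from 0) and percent of genes past the adjusted p threshold of 0.05 (right, higher in red and lower in blue) by the number of arrays on which a gene had a shared value (x axis, with the number of genes). The median rises from -0.03 to 0.54 and the share of lower calls falls from 15.5% to 0.14%.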

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

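The settings that left out genes with a shared value, centred within classes of shared values, removed the length trend, tested smaller families, applied fry to the families or applied fry to centred arrays were chosen after the data were examined. Of 5007 calls, 3882 passed after centring, 3913 after centring and scaling, 4909 after quantile normalization, 4962 with the robust prior and 4969 with array weights. The count of genes past the threshold was 8264 at an adjusted p under 0.10 (5118 higher, 3146 lower) and 0 without any 1 replicate, both higher (0) and lower (0), because 2 arrays left the smallest adjusted p at 0.0814 or more. Higher calls numbered 1920 after centring and 1951 after centring and scaling, and lower calls 3210 without shared values. At least 2-fold on every array, 861 genes were higher and 1222 lower after centring, and 880 and 1218 after centring and scaling. Without shared values 726 were higher and 769 lower, so the balance of these counts turned in all 3 settings. With 1 replicate left out the counts were 1833 to 1947 higher and 927 to 1179 lower. At 1.5-fold on every array there were 3128 and 1941. The mean correlation of the arrays was 0.80 without shared values, and with 1 replicate left out 0.55 to 0.59. The neuropeptide list did not pass with an estimated correlation (adjusted p = 0.632) or by fry on arrays centred on the named genes (0.0542); its shift of 1.17 is the same there by construction. By fry, which tests against 0 while the deposited ratios lie above it (other named genes' median 0.30), the chemoreceptor names (shift 0.21), oxidative phosphorylation (0.23) and PMK-1-responsive genes (0.19) passed; on centred arrays the first 2 passed (0.0412 and 0.00712) and the last did not (0.872). The count of families was 0 with an estimated correlation, 11 among families of 4 or more, 12 by fry and 0 by fry on centred arrays. Without replicate 2 it was 8, as the lido family gained the call (shift -0.50, camera adjusted p = 0.0307). Except where the alternative's own construction shows it, the cause was not tested. For the named genes, which include some never called, 133 of 574 values under alternatives lost the call, 2 gained it (irg-8 and ptr-25) and 0 reversed. Every called gene lost it with any 1 replicate left out, where 0 genes passed at all. Only M04D8.5, cox-19 and srsy-1 lost it under other settings as well. The dbd family lost the call without replicate 3, after centring within classes of shared values and without shared values, where 3 members were left. It did not pass among the 56 families of 4 or more (adjusted p = 0.0707). Rows with values on at least 2 arrays changed nothing to test, since missing probes lacked all 3 values. The filter on low intensity and the dkf-2 level were not run, as the table holds no intensities and no probe named dkf-2 was analysed here; the robust prior was not run for lists and families.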

Other observations

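The search over smaller families and all tests of explanations in this part were chosen after the results were seen. In the search over families of 4 or more, 5 further name stems stood below other named genes by camera with the preset correlation; 15 of their 31 members were called lower and 1 higher. With an estimated correlation 0 of the 56 families passed (adjusted p = 0.727 for each of these 5). By fry without centring, ints (adjusted p = 0.0490), prp (0.0495), nol (0.0495) and eif (0.0182) passed over the 56 families, and rbm (0.130) did not. Of 8 measured subunits of the Integrator complex, which cleaves nascent RNA at the polymerase, 4 fell and 8 of 8 had a negative mean, with ints-3 at -1.75 ± 0.19 and ints-13 at -1.28 ± 0.22 (n = 3; family adjusted p = 0.000644 over 56 families). Of 4 pre-mRNA processing genes 3 fell, with prp-40 at -1.66 ± 0.48 and prp-9 at -1.59 ± 0.50 (adjusted p = 0.00411), and of 4 nucleolar genes 2 fell, with nol-14 at -1.75 ± 0.40 (adjusted p = 0.00442). Of 7 genes named for translation initiation factors (eif) 3 fell, eif-2Bepsilon by the most at -1.85 ± 0.34 (adjusted p = 0.0309). Whether each of them is such a factor was not checked here. Of 8 RNA-binding motif genes 3 fell, with rbm-22 at -1.63 ± 0.39, and 1 rose, rbm-3.1 at 0.93 ± 0.13 (adjusted p = 0.0383). Other stems of RNA-related genes, gtf, trmt, metl and npp, did not pass at the preset correlation (adjusted p between 0.198 and 0.311).

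Among named genes without a shared value, the 551 genes on the X chromosome had a median log2 ratio of 0.36, with array medians of 0.37, 0.30 and 0.38, and 133 were higher and 41 lower. The 3724 autosomal genes had a median of 0.08, and the medians of chromosomes I to V lay between -0.09 and 0.17. The difference of 0.28 had a permutation p of 1e-04 over genes, the smallest that 10000 draws can give, and was 0.27 after the trend with gene length was removed. In the same set, 21 genes chosen for known germline roles after the data were examined had a median below that of other genes (difference -0.59, one-sided permutation p = 0.0114), with 6 called lower and 1 higher. Genes are not independent replicates. Shorter genes had higher ratios: the shortest 428 genes had a median of 0.67 and the longest 428 genes -0.11 (Spearman's rho -0.20 over 4275 genes).

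The 5007 calls were set against sign patterns of the arrays. Of the 4 patterns 1, the real one, gave as many genes, and the highest of the others gave 0 (limma; 156 to 185 genes at an unadjusted p under 0.05); 4 patterns are too few for a share under 0.05. A dye effect of single genes would repeat on every array and cannot be told apart from a difference between the strains, since the dyes were swapped on 0 arrays.

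More genes were called higher than lower (60.8% of the calls). If dim spots read higher in the Cy5 channel, genes without a shared value would lose the excess. Over genes and unnamed probes together 48.4% of their calls were higher, so dim spots may account for the excess there. Named genes without a shared value kept an excess in the same refit, with 1342 higher and 1008 lower. For named genes dim spots may thus account for only a part. An offset common to every spot of an array, as the whole cause, is argued against by the medians of genes without a shared value, the highest of which was -0.012 on the 3 arrays, against medians over all genes of 0.20, 0.22 and 0.12. A real excess of rises among weakly expressed genes in the transgenic strain stays open, as no intensities were used here.

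The 7 families of 10 or more genes that passed camera's test (6 higher, and the carboxylesterases lower) and the 5 smaller ones below other genes passed camera only with the preset correlation. With an estimated one, which 3 arrays leave little power, 0 of 17 and 0 of 56 families passed. The estimate was 0.59 for prp, 0.51 for nol and 0.44 for rbm, but -0.12 for ints and -0.16 for eif. By fry without centring, the 7 passed (adjusted p 0.0171 to 0.0461 over the 17). So did ints, prp, nol and eif (0.0182 to 0.0495 over the 56), but not rbm (0.130). After centring 0 of the 17 passed by fry, and the smaller families were not tested. For the 7, adjusted over the 17 families, dim spots as the whole cause are argued against by 6 that passed without genes with a shared value (dbd, with 3 members left, did not), and gene length by 7 that passed once its trend was removed (adjusted over the 56 families, spig at 0.0556 and dbd at 0.0558 did not pass); 6 passed with both removed. For ints, prp, nol, eif and rbm, adjusted over the 56 families, 2 of 5 passed without such genes, 5 of 5 without the length trend and 0 of 5 with both removed. The shifts kept most of their size: -0.77 for ints, -1.19 for prp, -0.61 for eif and -0.73 for rbm, against -1.13, -1.45, -0.86 and -0.86 before (nol had too few members left). The 8 ints, 4 prp and 7 eif genes had no shared value, and neither had 7 of the 8 rbm genes. Leaving out genes with a shared value thus changed mainly the genes that these families were compared with. A dim reading of the members' own spots was not marked for ints, prp and eif. For dim spots among the other genes together with length, these values neither exclude them nor count for them. A smaller share of germline RNA may also account for these 5. The 21 genes known for germline roles, without a shared value, had a median below that of other genes (difference -0.59, one-sided permutation p = 0.0114). Of these, 6 were lower, such as syp-5 at -1.13 ± 0.25, and 1 higher, znfx-1 at 1.09 ± 0.11. Their median of -0.46 lay above those of prp (-1.25), nol (-1.17), rbm (-0.93) and ints (-0.83) without shared values, and below that of eif (-0.19). These 5 families were picked for low ratios in the same data, so this comparison does not weigh for or against a germline share. A separate check concerned the carboxylesterases, several of which are known as intestinal enzymes. A smaller germline share with no other change would raise them. The 17 of them without a shared value lay below other such genes (difference of medians -1.26). Over all 31 the median was -0.34 against 0.31, with 11 positive. The 17 argue against a germline share as the whole cause for the carboxylesterases. The 5 smaller families were not tested by this. An effect of the DKF-2-GFP transgene and a dye effect of single genes stay open for all of these families, and a germline share for the 6 higher ones and the neuropeptide list. These arrays cannot tell an effect of the transgene apart from other differences between the strains.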
